A study of Saccharomyces cerevisiae BY4741 with 66 samples.

How the data were processed

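The study used selective ribosome profiling in Saccharomyces cerevisiae: cells were collected by filtration, frozen and milled, ribosome footprints of the whole lysate gave the total translatome, and footprints of ribosomes that came down with a GFP-tagged subunit on GFP antibody beads gave the IP translatome, per the labels' protocols. Of 66 libraries, 50 had a table of values per gene, 25 totals and 25 IPs of 15 strains. The others had files of values by position, which stood for the NAA10-GFP, NAA15-GFP, NAA20-GFP, NAA25-GFP, EGD1 and EGD2 strains and for a mix of FAS1-GFP and FAS2-TAP cells. Samples were grouped by the tagged strain and the fraction that their titles give, and replicate numbers come from the titles.

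Adapters were trimmed with cutadapt 1.8.3, per the submitters' processing notes. The aligner, the counting rule, the strand setting and the genome build are not given in the sources used here. The deposited tables have no header. Their values were taken as RPM, reads scaled to a fixed library total, because the low values of each deposited column are multiples of a single step and the columns sum to less than that total. The inverse of that step gave the implied number of reads, 0.544 to 55.9 M per library, and 37.8% to 96.5% of those reads lay over the listed genes, 73.0% to 96.5% in totals and 37.8% to 94.3% in IPs. Between 19.9% and 80.7% of a library's values were whole numbers of reads within 0.01 read, so read counts were not recovered and no test for counts was used, where the plan had allowed for counts. A flag in the deposited tables separates genes at 64 reads and was not used. The profile files hold a ratio of IP over total at each nucleotide, per the file headers of all but 2 files, which share the layout; how the authors scaled or smoothed it is not given. The file of the mix holds 2 unlabelled columns of values, treated as a score whose meaning the deposited file does not state. The deposited ratio along EGD1 has 45 undefined positions, which were left out.

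Each table listed 6605 features, of which 5919 matched a locus tag in the RefSeq table of assembly R64 and 5887 had the same coordinates there. Gene names come from that table, and coordinates are those of the deposited files. Nuclear features that overlap a non-coding RNA gene in that table numbered 45. The 28 mitochondrial features were left out of scaling and tests, because 19 libraries list all of them at 0. Overlapping and near-identical genes share reads in a way the sources do not describe, so features over tRNA or snoRNA genes and gene copies are uncertain.

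For the tests, values were scaled with an unweighted trimmed mean of log ratios (trim 0.3 on ratios and 0.05 on means), set to log2(value + 1), and restricted to features with a mean of at least 5 RPM over the libraries fitted. The 40 libraries of the 10 strains with 2 replicates were fitted in 1 model with a mean per strain and fraction by limma-trend, without a block, over 5135 features. Contrasts were IP minus total per strain, the same minus the mean over strains with a tagged subunit of another complex, the change of IP minus total with each MPT deletion, and totals of each deletion strain minus FAS1-GFP totals. Totals in SD-trp (3) were set against totals of full-length tagged strains in YPD (17) over 4936 features. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1. 18 lists of genes, written before the data were examined, were tested with camera in limma at a preset correlation of 0.01 and with an estimated correlation; ARG5 of the arginine list matched no name, which left 10 of 11. On simulated data with the design of GUS1-GFP IP against total (5049 genes, 200 changed, SD 0.35 on the log2 scale), the limma step recovered 92% of 100 genes changed by 1.5 log2 and 100% of 100 genes changed by 3 log2, with 7 false calls. The changed genes were drawn from the more abundant ones, and all groups otherwise had the same mean. The real GUS1-GFP replicates spread more widely, with an SD of their log2 difference of 0.97 in totals and 1.01 in IPs. Recovery in the real data can therefore be lower.

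Partner enrichment was tested with a two-sided permutation of the tags over 13 strains (100000 draws) on the log2 ratio of RPM over genes, plus 1, averaged over replicates. The value of 1 of the 19 ordered pairs, which is part of that mean, is not reported here. Profiles were summarised in 10 equal segments of the coding sequence, and the onset was the first codon of a window of 15 codons from which the running mean stayed at or above 2 times the mean of the first 60 codons. Subunits of the tagged complexes were always named. Further genes were named by a rule fixed before the data were examined: per strain, the 5 highest and 2 lowest called genes that moved the same way in both pairs, with a mean of at least 5 RPM; for changes of IP enrichment, 5 each way; for totals, the 10 highest and 10 lowest called genes and up to 4 called members of each list. LEU2, URA3 and cassette markers gave no tested value, and HIS3 and MET17 were named as markers. ARG1 and HSP12 in single libraries, summed mating-type genes and LYS2 were chosen after their values were seen.

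Alternatives tried were no further scaling, equal totals over genes, no filter, a pseudocount of 0.1, a replicate block, only the libraries of the strains in a contrast, no minimum fold change and each library of the strains in a contrast left out in turn (for SD-trp against YPD, each SD-trp library), and for the profiles and the mix other windows, thresholds, baselines and end positions. Chosen after seeing the data were mitochondrial features kept, features over non-coding RNA genes left out, the processing batch as a term, array weights, leaving out the FAS1-GFP FAS2dMPT replicate 2 pair or the FAS1-GFP replicate 2 pair, all YPD totals as reference, and SD-trp against YPD without the library labelled FAS1-GFP total 2. Software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.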

Results

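Selective ribosome profiling compares 2 pools of ribosome footprints. The total translatome samples all translating ribosomes, and the immunopurified (IP) translatome samples the ribosomes that come down with a GFP-tagged protein, so an mRNA can be more frequent in the IP because its nascent chains were held by the tagged protein. Some features were more frequent in the IP whichever subunit was tagged. The series held 66 libraries of Saccharomyces cerevisiae, strain BY4741 per the labels. Values per gene were analysed for 50 of them, 25 totals and 25 IPs from 15 strains, of which 10 had 2 replicates of both fractions and 5 had 1. The tagged proteins were subunits of fatty acid synthase (FAS1, FAS2), of the aminoacyl-tRNA synthetase complex (GUS1, MES1, ARC1), of phosphofructokinase (PFK1, PFK2), of anthranilate synthase (TRP2, TRP3), of carbamoyl phosphate synthetase (CPA1) and of the initiation factor eIF2 (SUI2, SUI3, GCD11). Cultures grew at 30 °C and 150 rpm in rich medium (YPD), except TRP2-GFP and TRP3-GFP in medium without tryptophan (SD-trp), CPA1-GFP in medium without arginine, and the MPT deletion strains FAS1dMPT-GFP and FAS1-GFP FAS2dMPT in medium with added fatty acids. Values per gene are in RPM, here reads per gene scaled to the reads over all nuclear genes unless they are called scaled values, which carry the trimmed-mean factors. Summed mating-type genes are scaled to the reads over all listed genes, mitochondrial ones included. The size of the smallest value step implied 1.74 to 55.9 M reads per total library and 0.544 to 31.7 M per IP library. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries. Each SE comes from the spread within all groups of a fit, so libraries of other strains enter it. All log2 differences are on the log2(value + 1) scale, which understates the change of low genes.

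The FAS1-GFP libraries address which nascent chains are bound by the beta subunit of fatty acid synthase, the enzyme complex that builds long-chain fatty acids. FAS2 (YPL231W, chromosome XVI, 108652 to 114315), the alpha subunit, rose from 2933 and 4367 RPM in the totals to 169100 and 312800 in the IPs. The log2 difference was 6.15 ± 0.61 (SE, 2 libraries against 2), 5.88 and 6.43 in the pairs of libraries with the same replicate number, with limma adjusted p = 1.37e-06. FAS1 itself (YKL182W, chromosome XI, 100671 to 106826) had a log2 difference of 0.85 ± 0.22 and was not called by limma, adjusted p = 0.124. Its direction turned to -0.21 with no further scaling. FAS2 was the 1 gene called among 5135 tested, and against the mean of the strains with a tagged subunit of another complex its log2 excess was 5.91 (limma adjusted p = 1.41e-05). The number of other genes called depended on the scaling: with no further scaling 13 genes were higher and 2536 lower, at a median log2 shift of -1.08 over all genes, and with each library set to the same total over genes 7 were higher and 142 lower. Against the other complexes 2 genes were called, FAS2 and the lower GUS1, and these settings gave 1 higher and 355 lower, and 1 higher and 74 lower. Without the library FAS1-GFP total 1 the count was 68, without IP 1 it was 12 and without IP 2 it was 2. This IP against total count was 4 without a filter, 40 with the spread estimated from this strain's libraries alone, 301 with a weight for each library and 552 with a replicate block. The count against other complexes also moved when single libraries were left out, and FAS2 kept its call there in each alternative.

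In FAS2-GFP, the reverse tag, the partner FAS1 was not called. It had a log2 difference of 0.21 ± 0.22 (SE, 2 libraries against 2; 0.23 and 0.20 in the pairs), with limma adjusted p = 0.485, and FAS2 itself of 1.61 ± 0.61, 1.53 and 1.69 in the pairs (limma adjusted p = 0.0787). The SE of FAS2 was the same in each strain and includes the spread of FAS1-GFP FAS2dMPT. There FAS2 stood at 141 and 355 scaled RPM in the libraries labelled total and 473.5 and 36.2 in those labelled IP. The direction for FAS1 in FAS2-GFP turned to -0.27 with no further scaling. In limma 316 genes were called, 108 higher and 208 lower, and the highest 4 were YOR072W-B (8.25), YNL042W-B (7.75), YJL047C-A (7.67) and YOL013W-A (6.60), open reading frames that overlap the tRNA or snoRNA genes SUF11, YNCN0009W, SNR60 and YNCO0011W. MTC7, a gene of unclear function, followed at 5.39. At the lower end were COX7 (-2.17), a subunit of cytochrome c oxidase, and CMC1 (-2.29), a factor for its assembly. Against the other complexes 2 genes were called, both lower, and they were GUS1 and MES1, whose reference mean includes the strains in which they were enriched, with 1 higher and 3 lower at equal totals over genes and 0 called with no further scaling. The 316 calls became 0 without the library FAS2-GFP IP 1, without total 2, or with the spread estimated from this strain's libraries alone, so each gene named here lost its call in those settings. With a weight for each library 786 genes were called. The calls split into 374 higher and 19 lower with libraries set to equal totals over genes, at a median log2 shift of 0.35, and into 30 higher and 638 lower with no further scaling, at -0.53. FAS2-GFP IP 2 held 202.6 RPM of summed MATa-specific genes (MFA1, MFA2, STE2, BAR1, STE6 and AGA2) where total 2 held 3.81.

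The aminoacyl-tRNA synthetase complex of yeast joins the glutamyl-tRNA synthetase GUS1 and the methionyl-tRNA synthetase MES1 through the cofactor ARC1. With GUS1-GFP, MES1 (YGR264C, chromosome VII, 1019598 to 1021853) rose by a log2 difference of 4.48 ± 0.25 (SE, 2 libraries against 2) and ARC1 (YGL105W, chromosome VII, 307437 to 308567) by 4.60 ± 0.34, and these 2 were the genes called by limma, at adjusted p = 4.48e-12 and 9.58e-10. With MES1-GFP, GUS1 (YGL245W, chromosome VII, 39023 to 41149) rose from 1989 and 1765 RPM to 56120 and 52200, a log2 difference of 4.51 ± 0.24, and ARC1 by 2.86 ± 0.34 (limma adjusted p = 1.37e-12 and 1.91e-05). With ARC1-GFP, GUS1 alone was called, at 3.35 ± 0.24 (limma adjusted p = 1.40e-09), and MES1 had 0.91 ± 0.25, 0.90 and 0.92 in the pairs, with limma adjusted p = 0.142 (1.31 and called with equal totals over genes). The tagged subunits themselves had log2 differences of -0.33, -0.30 and -0.39 for GUS1, MES1 and ARC1, none called. MES1-GFP had 2 further calls, with limma adjusted p = 0.0214 and 0.0418. They were YJL047C-A at 8.49, which overlaps the snoRNA gene SNR60, and INO1, inositol phosphate synthase, at 4.46. INO1 was called higher in 2 of the replicated strains. With TRP2-GFP it rose from 0.931 and 2.51 to 34.1 and 19.9 scaled RPM. HSP12, a stress-induced gene, also rose with MES1-GFP, from 8.40 and 8.73 to 139 and 168.6. The call of INO1 thus does not by itself show binding by MES1, and its cause was not tested. Against the strains with tagged subunits of other complexes the partners were called too, with log2 excesses of 5.19 for ARC1 and 4.51 for MES1 with GUS1-GFP, 5.001 for GUS1 and 3.46 for ARC1 with MES1-GFP, and 3.83 for GUS1 with ARC1-GFP, with no other gene called. With the libraries of GUS1-GFP alone neither partner was called, at log2 differences of 4.49 and 4.60, and ARC1 in MES1-GFP was not called with no further scaling (2.39, limma adjusted p = 0.0577). The count for GUS1-GFP was 31 without its IP 2 and 4 without its total 1, that for MES1-GFP was 2 without total 1, total 2 or IP 2, where INO1 and YJL047C-A lost their calls, and that for ARC1-GFP was 4 without IP 1. With the libraries of each strain alone MES1-GFP had 590 calls and ARC1-GFP 559, with a weight for each library 618 and 571, with a replicate block 504 and 464, and without a filter 7 and 15. Against other complexes the weights gave 39 for MES1-GFP and 75 for ARC1-GFP.

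Phosphofructokinase, which commits glucose to glycolysis, has the subunits PFK1 and PFK2. PFK2-GFP enriched PFK1 (YGR240C, chromosome VII, 970771 to 973734) from 2033 and 2157 RPM in the totals to 10800 and 22210 in the IPs, a log2 difference of 2.65 ± 0.29 (SE, 2 libraries against 2; 2.10 and 3.21 in the pairs; limma adjusted p = 8.80e-06). PFK1-GFP gave PFK2 (YMR205C, chromosome XIII, 671887 to 674766) a log2 difference of 1.34 ± 0.25, 1.92 and 0.76 in the pairs, which limma did not call, adjusted p = 0.0901. PFK1-GFP total 1 had 77.0% of its reads over genes, against 94.8% in total 2. Its closest library over all genes was SUI3-GFP IP 1 (r = 0.963). PFK1-GFP IP 2 had 89.1% over genes and r = 0.980 with its total 2. The smaller value of PFK2 thus does not by itself show weaker binding. In PFK1-GFP limma called 0 of 5135 genes, with 859 at an unadjusted p below 0.05. In PFK2-GFP limma called 528 genes, 371 higher and 157 lower. The highest besides PFK1 were YJL047C-A (7.18, over SNR60), PAN2 (2.43), a subunit of a poly(A) nuclease, SNT2 (2.37) and BPH1 (2.35), and the lowest SDH5 (-2.80), an assembly factor of succinate dehydrogenase, and PEF1 (-2.64). Over the 10 replicated strains PAN2, SNT2 and BPH1 were higher on average too, with mean log2 differences of 1.07, 1.18 and 1.22. Against other complexes 70 genes were called, 51 higher and 19 lower, led by PFK1 at 2.62 (limma adjusted p = 3.48e-05) and followed by SRB5, PTP3, YSH1 and MUB1 between 1.51 and 1.61. PFK1-GFP counted 905 genes without its IP 2 and 6 without its total 2, and PFK2-GFP 10 without its total 2, 89 without its total 1 and 316 without its IP 2, and 0 with its own libraries alone, where PFK1 had limma adjusted p = 0.0517. Without total 2 the named genes of PFK2-GFP other than PFK1 were not called. The 70 against other complexes became 1 without its total 2, 218 without its IP 1 and 185 without its IP 2. They became 11 or fewer without its total 1, FAS1-GFP total 1 or IP 1, or any total of MES1-GFP, ARC1-GFP or TRP2-GFP, and 36 to 155 without any other library of the strains compared. With a weight for each library 1 gene was called there. The PFK2-GFP split was 505 higher and 65 lower with equal totals over genes and 301 higher and 29 lower with no further scaling. Against other complexes these were 1 higher and 0 lower, and 229 higher and 1 lower. IP 1 of PFK2-GFP was the shallowest library, at 0.544 M implied reads.

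Anthranilate synthase, the first enzyme of the tryptophan branch, consists of TRP2 and TRP3. TRP2-GFP enriched TRP3 (YKL211C, chromosome XI, 36699 to 38153) from 228.5 and 248.6 RPM to 4877 and 5324, a log2 difference of 3.93 ± 0.29 (SE, 2 libraries against 2; 3.95 and 3.91 in the pairs; limma adjusted p = 1.86e-09). TRP2 itself (YER090W, chromosome V, 337949 to 339472) had 0.36 ± 0.26 and was not called. In limma 214 genes were called, 98 higher and 116 lower, with STE6, the a-factor exporter, at 5.23, STE2, the alpha-factor receptor, at 5.14 and YGP1, a secreted glycoprotein, at 3.47 among the highest, and SRN2 (-2.22) and SPL2 (-2.20) at the lower end. Summed MATa-specific genes stood at 8.38 and 15.7 RPM in the TRP2-GFP totals and at 505.5 and 517.6 in its IPs, beside 2391.7 and 2327.1 against 699.4 and 801.8 for summed MATalpha-specific genes (MF(ALPHA)1, MF(ALPHA)2 and STE3). Against other complexes 7 genes were called, 3 higher, which were TRP3 at 4.08 and the polyamine transporters TPO2 at 2.79 and TPO4 at 2.75, and 4 lower, among them CIA1 (-1.38), of cytosolic iron-sulfur assembly, and ATG27 (-1.30), of autophagy. Of the genes named here TRP3 alone was called whichever TRP2-GFP library was left out, and the 7 against other complexes became 1 without total 1, total 2 or IP 2 and 39 without FAS1-GFP total 1. The 214 calls fell to 2, 3, 10 and 11 when IP 2, total 1, IP 1 and total 2 were left out in turn, and they split into 345 higher and 21 lower with equal totals over genes, at a median log2 shift of 0.44, and 12 higher and 0 lower with no further scaling. Against other complexes these splits were 18 higher and 0 lower, and 3 higher and 0 lower. With a weight for each library 712 genes were called, and 186 against other complexes, and with the libraries of TRP2-GFP alone 696.

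Across the 13 strains with a full-length tagged subunit, footprints of the untagged partners were enriched on average. The mean log2 ratio of IP over total was 2.07 over 19 ordered pairs of a tagged subunit and a partner, with 15 of the 19 above 0. Exchanging the tags between strains gave a mean of 0.29 and never reached that value (two-sided permutation test with 100000 draws, p = 1e-05, the smallest these draws can give). On this scale FAS2 in FAS1-GFP ranked first of 13 strains at 6.01, and FAS1 in FAS2-GFP ranked 3 of 13 at 0.63. TRP2 in TRP3-GFP had -0.32, against 4.41 for TRP3 in TRP2-GFP, and ranked 10 of 13. Of the 6 pairs within eIF2, SUI3 in GCD11-GFP had 1.30 and ranked first, from 395 to 976 RPM, and the other 5 lay between -0.17 and 0.19. TRP3-GFP and the eIF2 strains had 1 pair of libraries each, so these values have no replicate check.

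**Figure D1:**
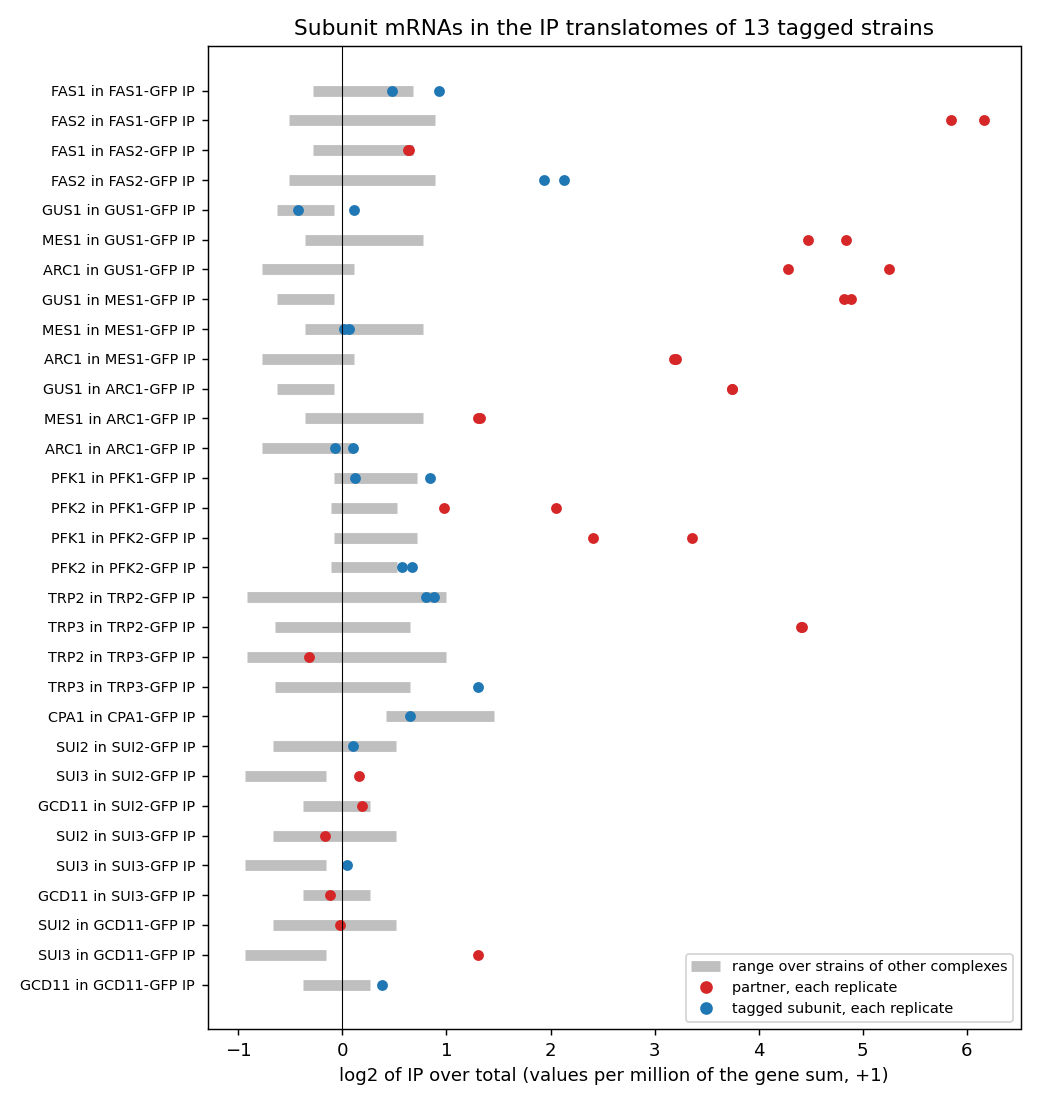
Log2 ratio of IP over total (x axis, from RPM over genes, plus 1) for subunits in the IP of strains with a tagged subunit (y axis), each point 1 pair of libraries, with partners in red, tagged subunits in blue and the range over strains of other complexes in grey. FAS2 in FAS1-GFP lies at 5.85 and 6.16, and FAS1 in FAS2-GFP at 0.64 and 0.63.

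The MPT deletions address whether the enrichment of FAS2 depends on the assembly domain of fatty acid synthase to which both subunits contribute. FAS1dMPT lacks 1165 base pairs of FAS1 that end at base pair 6153, and FAS2dMPT lacks the first 282 base pairs of FAS2, per the labels. Values per gene cannot check the FAS1 deletion, since most of the gene is still there: FAS1 stood at 3404 and 3682 scaled RPM in the FAS1dMPT-GFP totals. FAS2 stood at 141 and 355 in the libraries labelled FAS1-GFP FAS2dMPT total 1 and total 2, against 3319 and 4202 in the FAS1-GFP totals. The 282 base pairs are a small part of FAS2, so these values do not check that deletion either, and their fall is larger than the missing part would give. The IP change of FAS2 in this strain is thus measured on few FAS2 footprints. The IP difference of FAS2 fell by 5.59 ± 0.87 log2 (SE) in FAS1dMPT-GFP (limma adjusted p = 0.00465). In FAS1-GFP FAS2dMPT it fell by 6.91 ± 0.87 (limma adjusted p = 0.00012), and FAS2 was the 1 gene called in each. The size of this fall rests on the pair labelled replicate 2, whose total and IP labels may be exchanged. If they are, FAS2 was higher in the IP in both pairs of FAS1-GFP FAS2dMPT, and the fall was smaller. Such a rise would not by itself show binding. The library FAS1-GFP FAS2dMPT IP 1 also held more summed MATa-specific genes than its total 1, at 81.2 against 9.44 RPM. Without the replicate 2 pair of FAS1-GFP FAS2dMPT, an alternative chosen after seeing the data, this change was -4.41 (limma adjusted p = 3.0e-05). Within FAS1dMPT-GFP the FAS2 difference was 0.56 ± 0.61, 0.08 and 1.04 in the pairs, and 0 of 5135 genes were called by limma, with 259 at an unadjusted p below 0.05 and 98 called without its IP 1. The library FAS1dMPT-GFP IP 1 had 91.5% of its reads over genes, against 95.8% in total 1, and was closest to that total over all genes (r = 0.992). Within FAS1-GFP FAS2dMPT it was -0.76 ± 0.61, and the pairs went apart, at 1.74 for the pair labelled replicate 1 and -3.26 for the pair labelled replicate 2, with 0 genes called by limma and 87 at an unadjusted p below 0.05, and 64 called without the library labelled IP 2. For FAS1dMPT-GFP the call was lost with no further scaling (-4.59, limma adjusted p = 0.0711), without the FAS1-GFP replicate 2 pair (-5.24, limma adjusted p = 0.352), without FAS1-GFP IP 2 (-5.10, 0.117), FAS1dMPT-GFP total 1 (-5.46, 0.0559) or FAS1dMPT-GFP IP 1 (-5.25, 0.0848), and the count was 12 without FAS1-GFP total 1. For FAS1-GFP FAS2dMPT it was lost with the libraries of these 2 strains alone (-6.87, limma adjusted p = 0.957). Medium with fatty acids cannot be told apart from either deletion. Strain background is a further difference. The FAS1dMPT-GFP libraries carried the MATa pattern, while FAS1-GFP total 1 and both FAS1-GFP IPs carried mainly MATalpha genes. The replicates of FAS1-GFP FAS2dMPT differed from each other in this pattern.

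The total translatomes of the deletion strains, grown with added fatty acids, were set against those of FAS1-GFP to ask what else differed. The library labelled FAS1-GFP FAS2dMPT total 2 may be an IP library, since the labels of its pair may be exchanged. The labels were used as given. In FAS1dMPT-GFP 59 genes were called, 46 higher and 13 lower, and in FAS1-GFP FAS2dMPT 142, 96 higher and 46 lower. NQM1, a transaldolase paralog, rose by 5.27 ± 0.57 log2 (SE, 2 libraries against 2) in the former and 6.12 ± 0.57 in the latter (limma adjusted p = 5.93e-06 and 2.81e-07). INO1, which makes inositol phosphate for phospholipids, rose by 5.06 ± 0.89 and 5.70 ± 0.89 (limma adjusted p = 0.00229 and 0.000232), HXT5, a hexose transporter, by 3.64 and 4.11, and TKL2, a transketolase, by 3.31 and 4.72. PHM7 rose by 3.54 and 4.15 and FMP45 by 3.39 and 4.24, and the drug exporter PDR15 by 3.88 in FAS1dMPT-GFP. OLE1, the fatty acid desaturase, rose by 1.77 ± 0.38 and 1.60 ± 0.38 (limma adjusted p = 0.0129 and 0.0144). FAS2 fell by 4.05 ± 0.61 in FAS1-GFP FAS2dMPT (limma adjusted p = 0.000194) and had -1.24 ± 0.61 in FAS1dMPT-GFP, not called, while FAS1 had 0.05 and -0.32.

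Genes of phosphate and purine supply were among those that fell most. In FAS1-GFP FAS2dMPT the acid phosphatases PHO11 (-3.37), PHO12 (-3.11) and PHO5 (-2.93) and the phosphate transporter PHO84 (-3.00) fell, and SPL2, a regulator of phosphate uptake, had -3.04 there and -2.37 in FAS1dMPT-GFP. PHO11 and PHO12 are near-identical copies, so their reads can be shared. PHO84 stood at 1459 scaled RPM in FAS1-GFP total 1 and at 198.8 in the library labelled FAS1-GFP total 2, and without FAS1-GFP total 1 it had -1.55 and PHO11 -1.64, both called, and PHO5 -1.98 and PHO12 -1.16, not called. VTC3 (-1.87) and VTC4 (-1.35), of the polyphosphate polymerase, fell in FAS1dMPT-GFP, and VTC1 (-1.64) in FAS1-GFP FAS2dMPT. ADE17, of purine synthesis, had -1.89 in FAS1dMPT-GFP and -2.77 in FAS1-GFP FAS2dMPT, and ADE12 had -1.29 and IMD2, of guanine nucleotide synthesis, -1.501 in the former. YHB1, a nitric oxide dioxygenase, had -2.21 and -3.08, IRC7, a cysteine desulfhydrase, -2.11 and -2.23, and PDR12, an organic acid exporter, -2.44 in FAS1dMPT-GFP. No list for phosphate or purine genes was fixed beforehand, so these are single genes.

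**Figure D2:**
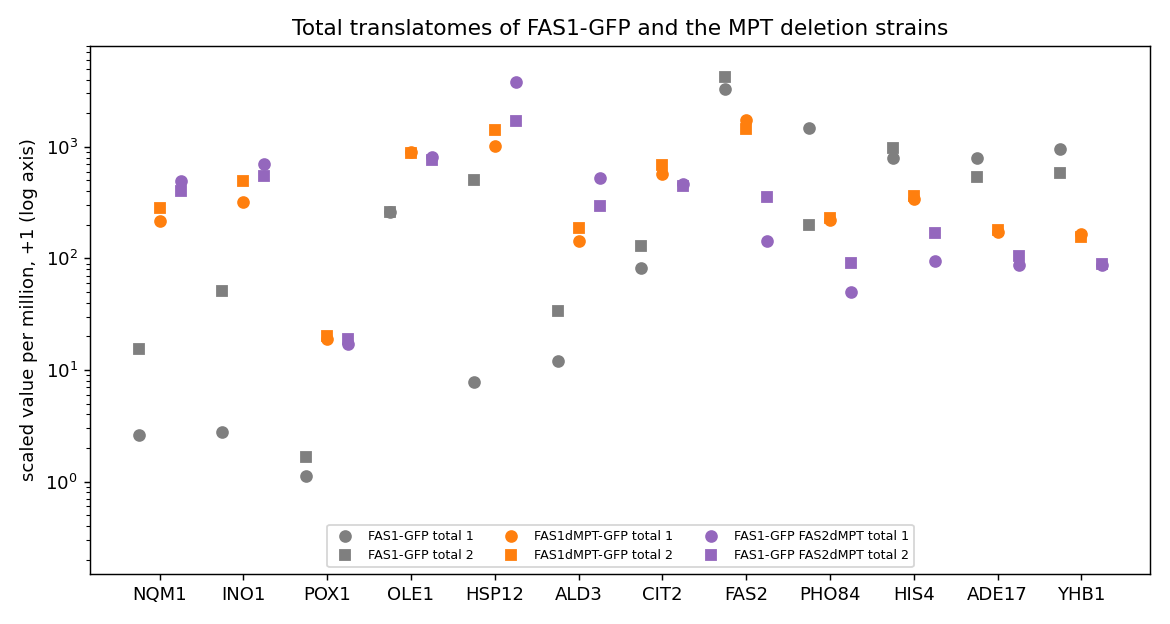
Scaled values in RPM, plus 1, on a log axis (y axis) for 12 genes (x axis) in the 2 total libraries each of FAS1-GFP (grey), FAS1dMPT-GFP (orange) and FAS1-GFP FAS2dMPT (purple). HSP12 differs between the FAS1-GFP totals, at 6.79 and 503, and FAS2 lies at 141 and 355 in FAS1-GFP FAS2dMPT.

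Among the gene lists fixed before the data were examined, peroxisomal beta-oxidation, the pathway that degrades fatty acids, rose in both comparisons. Of its 15 measured members 2 were called higher in FAS1dMPT-GFP and 4 in FAS1-GFP FAS2dMPT (6 and 8 when adjusted over the list alone), and none lower. POX1, the acyl-CoA oxidase, rose by 3.83 and 3.71 and CIT2, the peroxisomal citrate synthase, by 2.60 and 2.14, with SPS19 (2.35) and FAA2 (2.01) in FAS1-GFP FAS2dMPT. The list tests (camera in limma) gave adjusted p = 1.42e-09 and 1.52e-09 with the preset correlation and adjusted p = 0.000749 and 0.000816 with an estimated correlation. Stress-induced genes had 3 of 25 called higher in FAS1dMPT-GFP and 13 in FAS1-GFP FAS2dMPT (13 and 23 when adjusted over the list alone), with ALD3, an aldehyde dehydrogenase, at 3.02 and 4.27, GRE1 at 3.28 and 3.85, HSP30 at 3.21 in the former, and HSP12 at 5.33 and DDR2 at 3.38 in the latter. Their camera call in limma was lost in FAS1dMPT-GFP with an estimated correlation, adjusted p = 0.115, and passed in FAS1-GFP FAS2dMPT, adjusted p = 0.0318. The list of other amino acid synthesis fell in FAS1-GFP FAS2dMPT, with 9 of 41 members called lower, among them HIS4 (-2.81), HIS1 (-1.94), ILV3 (-1.59) and LEU9 (-1.32), and camera in limma gave adjusted p = 0.0343 with an estimated correlation. In FAS1dMPT-GFP 0 of these 41 were called, with camera in limma at adjusted p = 0.000411 with the preset and adjusted p = 0.357 with an estimated correlation. HSP12 stood at 6.79 scaled RPM in FAS1-GFP total 1 and at 503 in the library labelled FAS1-GFP total 2.

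The remaining lists gave no call that held with an estimated correlation. Cytosolic ribosomal proteins (138 measured, 0 called) had median log2 differences of -0.48 and -0.55, tRNA synthetases (22, 0 called) of -0.46 and -0.57 and initiation factors (25, 0 called) of -0.35 and -0.44. Camera in limma called all 3 lower with the preset correlation, the weakest at adjusted p = 9.64e-05, and with an estimated correlation none, at adjusted p = 0.357 and 0.667, 0.248 and 0.129, and 0.357 and 0.371. In FAS1dMPT-GFP phospholipid and inositol synthesis, arginine synthesis, with CPA1 called at 2.19, and membrane and secreted proteins were called higher, and tryptophan and aromatic synthesis, glycolysis, chaperones and the respiratory chain lower, all with the preset correlation only (limma adjusted p = 0.338, 0.357, 0.357, 0.338, 0.521, 0.521 and 0.624 with an estimated correlation). In FAS1-GFP FAS2dMPT tryptophan and aromatic synthesis was lower with the preset correlation only (limma adjusted p = 0.237 with an estimated correlation). Fatty acid synthesis and elongation, ergosterol synthesis and the proteasome were called in neither comparison, and PDC5, of the glycolysis list, had -1.30 and -1.40, both called. Genes of mating type differed between libraries of one strain: summed MATalpha genes stood at 1603 RPM in FAS1-GFP total 1 and 3.82 in the library labelled total 2, and at 1149 and 5.42 in FAS1-GFP FAS2dMPT total 1 and total 2, while both FAS1dMPT-GFP totals carried the MATa pattern. Their medians were -3.20 for MATalpha and 2.92 for MATa genes in FAS1dMPT-GFP, with limma adjusted p = 0.338 and 0.342 with an estimated correlation, and -0.31 and -0.14 in FAS1-GFP FAS2dMPT.

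These counts rested on few control libraries, and both comparisons share the FAS1-GFP totals, so genes that moved in both are not independent observations. Leaving out FAS1-GFP total 1, the library labelled FAS1-GFP total 2, and the strain's own total 1 and total 2 in turn gave 6, 114, 13 and 10 calls for FAS1dMPT-GFP, and without FAS1-GFP total 1, and the strain's own total 1 and total 2, 53, 49 and 88 for FAS1-GFP FAS2dMPT. With the libraries of the strains compared alone the counts were 18 and 34, and with a weight for each library 214 and 232. For FAS1dMPT-GFP the count was 38 with a pseudocount of 0.1 and 108 without the FAS1-GFP replicate 2 pair. Against the 17 totals of all full-length tagged strains in YPD 335 and 409 genes were called, with NQM1 at 6.44 and 7.21, INO1 at 6.82 and 7.37, CIT2 at 2.71 and 2.17, OLE1 at 1.72 and 1.47 and FAS2 at -1.06 and -3.95. Scaling shifted the median of all genes by up to 0.29: with equal totals over genes the splits were 70 higher and 11 lower and 135 higher and 31 lower, and with no further scaling 66 higher and 4 lower and 81 higher and 19 lower. Of the genes named for FAS1dMPT-GFP, NQM1, HXT5, CIT2 and ALD3 were called whichever of the 4 totals compared was left out, PDR15 lost its call without the strain's own total 1 or total 2, and all others lost theirs without FAS1-GFP total 1 (INO1 2.95, limma adjusted p = 0.262; POX1 3.53, 0.098; OLE1 1.75, 0.199). For FAS1-GFP FAS2dMPT, HSP12 (2.35, limma adjusted p = 0.549), OLE1 (1.61, 0.131), DDR2, FAA2, SPS19, FMP45, PHM7, PHO5, PHO12, SPL2, VTC1, ILV3, LEU9 and PDC5 lost their calls without FAS1-GFP total 1.

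The comparison of media asks what differs between totals from medium without tryptophan and from rich medium. TRP2 had a log2 difference of 0.05 ± 0.19 (SE, 3 libraries in SD-trp against 17 in YPD) and TRP3 of 0.73 ± 0.20 (limma adjusted p = 0.966 and 0.689), and the sign for TRP2 turned to -0.03 with no further scaling. Of 4936 genes limma called 0, with 337 at an unadjusted p below 0.05, and with a weight for each library it called 43. Arginine synthesis (10 measured, median 0.66), the respiratory chain and citric acid cycle (34, 0.23), other amino acid synthesis (41, 0.18), tryptophan and aromatic synthesis (12, 0.19), stress-induced genes (23, 0.35) and phospholipid and inositol synthesis (19, 0.14) were called higher, and ergosterol synthesis (22, -0.19) and membrane and secreted proteins (30, -0.13) lower, by camera in limma with the preset correlation. None held with an estimated correlation, where the smallest adjusted p in limma was 0.454. MATalpha genes had a median of 3.58 and MATa genes of -2.51, since both TRP2-GFP totals carried the MATalpha pattern, and limma gave adjusted p = 0.566 for both lists with an estimated correlation. The other 8 lists were called by neither test. Medium and strain cannot be told apart here. ARG1, of arginine synthesis, stood at 1144 scaled RPM in TRP3-GFP total 1 and 1335 in CPA1-GFP total 1 from medium without arginine, against 222 and 184 in the TRP2-GFP totals. Among the YPD totals it stood at 56.3 in FAS1-GFP total 1 and at 1062 in the library labelled FAS1-GFP total 2, whose closest library over all genes was TRP3-GFP total 1 (r = 0.995).

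Profiles along single coding sequences, as the authors' ratio of IP over total at each position, were analysed for subunits of the N-terminal acetyltransferases NatA (NAA10, NAA15) and NatB (NAA20, NAA25) and of the nascent polypeptide-associated complex (EGD1, EGD2), with 1 profile each and no replicate. NAA10-GFP along NAA15 rose from a mean ratio of 0.256 in segment 1 of 10 equal segments to 81.5 in segment 6 and 260.2 in segment 10, and stayed above 2 times its start from codon 188 of 854. The same file was deposited with NAA15-GFP. NAA25-GFP along NAA20 rose from 0.123 in segment 1 to 1156 in segment 10, from codon 60 of 195. Both EGD1d11 strains also carried natNT2 at Btt1, per the labels. EGD1d11-GFP, with the first 33 base pairs of EGD1 deleted, rose along EGD1 from codon 116 of 158 to 32.8 in segment 10, and EGD1d11 EGD2-GFP, with EGD2 tagged and the same deletion, rose along EGD2 from codon 88 of 175, with means of 28.6 to 50.9 in the last 4 segments. NAA20-GFP showed no such onset along NAA20 or NAA25, where 77.0% and 79.6% of positions were 0 and the means of segment 10 were 0.657 and 0.141. With a window of 30 codons it had an onset along NAA20, at codon 143. The onset is the first codon of a 15-codon window, so the threshold can be passed up to 15 codons further on. The means of the first 60 codons were 0.186 to 0.32 in profiles with an onset, so the threshold lay below a ratio of 1. The steep rise came later. Along NAA15 the mean was 1.27 in segment 3 and 6.69 in segment 5, before the 81.5 of segment 6. For NAA25-GFP along NAA20 it was 0.633 in segment 4 and 122.2 in segment 7. The depth behind these ratios is unknown.

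**Figure D3:**
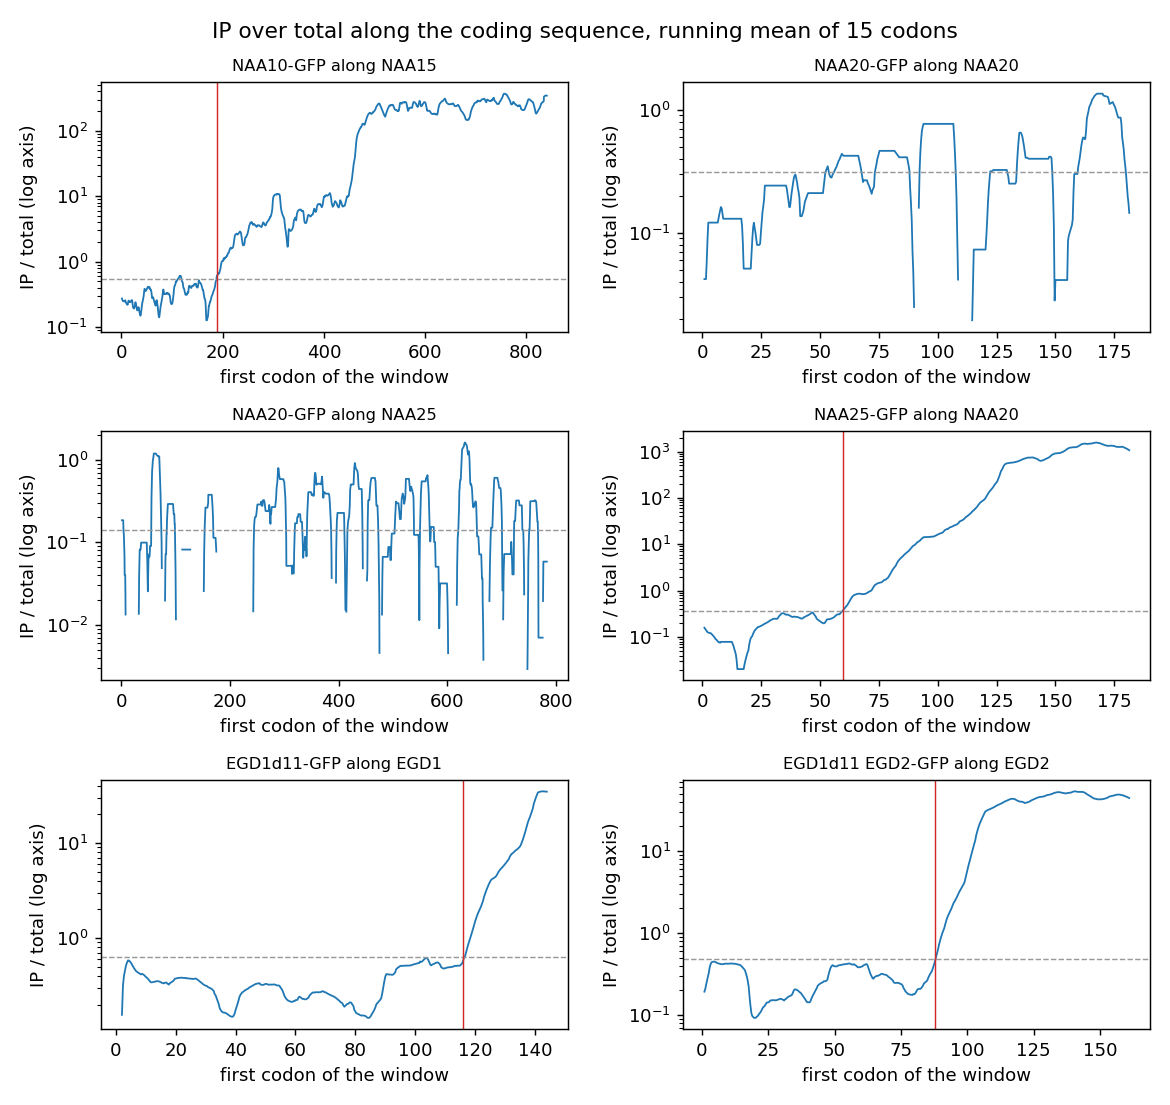
Running mean over 15 codons of the ratio of IP over total (y axis, log scale; gaps are windows at 0) against the first codon of the window (x axis) for 6 profiles. The dashed line is 2 times the mean of the first 60 codons, and the red line marks the onset, at codons 188, 60, 116 and 88 in the 4 profiles that have it.

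In the mix of FAS1-GFP cells with cells carrying FAS2 with a TAP tag, the question is whether FAS1-GFP also binds FAS2 chains made by the other cells after lysis. Both replicates carried the same file, with 2 unlabelled columns of values, whose positions run 192 beyond the 1888 codons of FAS2. The mean value was 27.8 and 28.7 within those 1888 codons and 5.64 and 6.47 over the 192 positions beyond them, of which 73 and 57 were 0. What the columns hold, and that the positions beyond FAS2 are the TAP tag, are read from the length alone, so no test was made.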

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

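Of the results in this part, all tests of the 3 patterns, the values without the FAS1-GFP FAS2dMPT replicate 2 pair and the sum of mitochondrially encoded genes were chosen after the data were seen. The others come from contrasts fixed before the data were examined. MET17, LYS2 and summed mating-type genes are in RPM over all listed genes, mitochondrial ones included.

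Of the 11 partners in strains with a full-length tag and 2 replicates, 8 stood apart from strains with a tagged subunit of another complex, by a test of the difference itself in limma, and FAS1 with FAS2-GFP (0.16), MES1 with ARC1-GFP (0.94) and PFK2 with PFK1-GFP (1.48) were not called. The limma adjusted p for PFK2 was 0.0522, and among the omissions of single libraries it was called without PFK1-GFP total 2 or IP 2, FAS1-GFP total 1 or total 2, FAS1dMPT-GFP IP 2 or GUS1-GFP IP 2. Strains with 1 replicate were not in this test. FAS2 had a log2 excess of 5.913 with FAS1-GFP. With GUS1-GFP it was 5.192 for ARC1 and 4.512 for MES1, with MES1-GFP 5.001 for GUS1 and 3.456 for ARC1, and with ARC1-GFP 3.833 for GUS1. PFK1 had 2.619 with PFK2-GFP and TRP3 4.079 with TRP2-GFP. The enrichment of FAS2 differed between FAS1-GFP and the deletion strains by -5.593 in FAS1dMPT-GFP and by -6.912 in FAS1-GFP FAS2dMPT, the latter by -4.412 without the replicate 2 pair.

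Other genes stood apart in the same test. GUS1 had -1.505 with FAS1-GFP, and GUS1 -1.979 and MES1 -1.704 with FAS2-GFP, and the reference of these includes the synthetase strains in which both genes were enriched. Some omissions of a single library removed the call of GUS1 with FAS1-GFP or calls with FAS2-GFP, while the values stayed negative. With no further scaling neither gene was called with FAS2-GFP. With PFK2-GFP, SRB5 had 1.61, PTP3 1.575, YSH1 1.518, MUB1 1.51, MIN9 -2.53 and ATR1 -2.519, and none of these 6 was called without PFK2-GFP total 1 or total 2. With TRP2-GFP, TPO2 had 2.791, TPO4 2.746, CIA1 -1.382 and ATG27 -1.296, and none of these 4 was called without TRP2-GFP total 1, total 2 or IP 2. Outside the main measurement, the summed mitochondrially encoded genes were higher in the IP in 14 of 15 pairs with values, with a median log2 ratio of 2.639, and the exception was the FAS1-GFP FAS2dMPT replicate 2 pair (-1.826). If the total and IP labels of that pair are exchanged, there is no exception.

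In the FAS1-GFP FAS2dMPT replicate 2 pair, FAS2 was lower in the library labelled IP than in that labelled total. The 50 features most enriched over the other 9 strains had a median log2 ratio of -1.942 in this pair, with 50 of 50 below 0, against 1.538 in the replicate 1 pair. That argues against a failed IP that gave a second total, for which values near 0 were needed. A candidate explanation is that the total and IP labels of this pair are exchanged, and the library labelled IP also had the larger share of reads over genes, 94.3% against 88.5%. Without this pair FAS2 had a log2 difference of 1.741 in this strain. With the labels exchanged FAS2 would be higher in the IP in this pair too, and its fall against FAS1-GFP would be smaller than reported. A rise of FAS2 in these IPs would not by itself show binding. IP 1 of this strain also held summed MATa-specific genes at 81.2 RPM, against 9.44 in total 1. The labels were used as given.

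All libraries are labelled BY4741, a MATa strain without MET17 and with LYS2, but FAS1-GFP total 1, IP 1 and IP 2, all FAS2-GFP libraries, replicate 1 of FAS1-GFP FAS2dMPT and the TRP2-GFP totals carried mainly MATalpha genes. The library labelled FAS1-GFP total 2 had the pattern of that label, with MET17 at 1.04 and LYS2 at 538.5 RPM against 912.4 and 0.111 in total 1. Its summed MATalpha genes stood at 0.002386 of their level in total 1, which argues against a minority of reads from another culture, and its MATa genes at 943.4, within the 627.7 to 1204 of 13 totals from other strains. These opposite mating-type and marker patterns argue against 1 shared strain for the 2 FAS1-GFP totals. FAS1-GFP IP 2 held summed MATalpha genes at 721 and MATa genes at 100, so the replicate 2 pair set unlike patterns against each other. The FAS1-GFP FAS2dMPT totals, for which no such test was made, also differed, with MATalpha genes at 1149 and 5.42. Both TRP2-GFP IP libraries held MATa and MATalpha genes, as a mixture of reads would give, and no biological explanation was tested. Against single-type IP libraries the shares were 0.5714 and 0.5851 for MATa and 0.6028 and 0.6911 for MATalpha genes. Parts of a mixture would add up to the whole, and these shares exceed it, so they do not measure the parts.

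Across strains 196 features had a mean log2 difference of at least 1 between IP and total, and 10 of -1 or less. The share going up was 0.9515, where lower depth of the IP libraries alone was predicted to move like numbers both ways. This share largely restates the pattern that prompted the test, and depth was not varied, so it does not decide on depth. Of the 196, 13 overlapped a non-coding RNA gene, against 24 of 5135 (two-sided Fisher exact p = 4.25e-13), but 93.37% overlapped none. The filter used the mean over totals and IPs, so features high only in the IP could pass it. Of 45 nuclear features over such genes, 24 passed. The test thus cannot decide whether reads of overlapping non-coding RNAs contribute. The set of 196 was defined by its mean after a first definition, features called higher in 5 or more strains, had given none.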

How the results depend on the processing

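Array weights, the reference of all YPD totals, the omission of the replicate 2 pairs, the batch term, the mitochondrial features and the features over non-coding RNA genes were chosen after seeing the data. Over 144 values of named genes, 3555 alternative values were computed, of which 3087 had the direction and the side of the threshold of the value reported, 420 lost the call, 19 gained it and 29 changed sign. The mean partner enrichment was called in each of its alternatives, from a mean log2 of 1.293 without the synthetase complex (permutation p = 0.00016) to 3.435 with replicate 2 alone (7e-05). With 2 libraries per group most counts depended on single libraries, and a lone library left in a group is assumed to vary like the other groups. Depths of 0.544 to 55.9 M reads limit low genes most in the IPs. Where no reason is given, the cause was not tested.

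With no further scaling, the IP against total counts were 2549 for FAS1-GFP, 668 for FAS2-GFP, 2 for MES1-GFP, 3 for ARC1-GFP, 330 for PFK2-GFP and 12 for TRP2-GFP, and against other complexes 356 for FAS1-GFP, 0 for FAS2-GFP, 230 for PFK2-GFP and 3 for TRP2-GFP. FAS1 turned to -0.2143 in FAS1-GFP and -0.266 in FAS2-GFP, and against other complexes to -0.09247 and -0.1442. ARC1 in MES1-GFP had 2.394 and was not called. For the change with the deletion in FAS1dMPT-GFP the count was 0, with FAS2 at -4.589 and FAS1 at 0.2574, and FAS1 had 0.471 in FAS1-GFP FAS2dMPT. TRP2 in SD-trp had -0.02842.

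With equal totals over genes, the counts were 149 for FAS1-GFP, 6 for ARC1-GFP, 1 for PFK1-GFP and 366 for TRP2-GFP, with MES1 at 0.03885 in MES1-GFP and ARC1 at 0.0118 in ARC1-GFP. Against other complexes they were 75 for FAS1-GFP, 4 for FAS2-GFP, 1 for FAS1dMPT-GFP (FAS1 -0.1608), 1 for FAS1-GFP FAS2dMPT, 1 for PFK2-GFP and 18 for TRP2-GFP. Without a filter they were 4 for FAS1-GFP, 7 for MES1-GFP and 15 for ARC1-GFP, against other complexes 5 for FAS2-GFP, 2 for ARC1-GFP and 20 for TRP2-GFP, and 2 for the change in FAS1-GFP FAS2dMPT. With a pseudocount of 0.1 they were 2 for MES1-GFP and 38 for the FAS1dMPT-GFP totals.

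With array weights, the counts were 301 for FAS1-GFP, 786 for FAS2-GFP, 26 for FAS1dMPT-GFP, 618 for MES1-GFP, 571 for ARC1-GFP and 712 for TRP2-GFP. Against other complexes they were 1 for FAS1dMPT-GFP, 39 for MES1-GFP, 75 for ARC1-GFP, 1 for PFK2-GFP and 186 for TRP2-GFP. For totals they were 214 in FAS1dMPT-GFP, 232 in FAS1-GFP FAS2dMPT and 43 in SD-trp, with TRP2 at -0.2545.

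Same-numbered totals and IPs deviated together with correlations over genes of 0.001 in ARC1-GFP to 0.834 in GUS1-GFP. The limma tests were planned and made without a block, and differences in pairs only set libraries with the same number side by side. With a replicate block the counts were 552 for FAS1-GFP, 962 for FAS2-GFP, 1 for FAS1dMPT-GFP, 504 for MES1-GFP, 464 for ARC1-GFP, 919 for PFK2-GFP and 621 for TRP2-GFP. Against other complexes they were 43 for FAS1-GFP, 33 for FAS2-GFP, 1 for FAS1dMPT-GFP, 1 for FAS1-GFP FAS2dMPT, 14 for MES1-GFP, 7 for ARC1-GFP, 1 for PFK1-GFP, 210 for PFK2-GFP and 113 for TRP2-GFP. For the change with the deletions they were 3 in FAS1dMPT-GFP and 6 in FAS1-GFP FAS2dMPT.

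With only the libraries of the strains in the contrast, which leaves fewer samples for the spread, the counts were 40 for FAS1-GFP, 0 for FAS2-GFP, 0 for GUS1-GFP (ARC1 4.6 and MES1 4.49), 590 for MES1-GFP, 559 for ARC1-GFP, 0 for PFK2-GFP (PFK1 2.623) and 696 for TRP2-GFP. The change with the deletion gave 2 in FAS1dMPT-GFP and 0 in FAS1-GFP FAS2dMPT (FAS2 -6.872), and totals gave 18 and 34.

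Without the FAS1-GFP FAS2dMPT replicate 2 pair, that strain's count was 5, with FAS1 at -0.01838 and FAS2 at 1.741, and against other complexes 1, with -0.07336 and 1.501, beside 1 for FAS1dMPT-GFP and 2 for ARC1-GFP. Without the FAS1-GFP replicate 2 pair, the count was 15 for MES1-GFP and, against other complexes, 1 for FAS1-GFP, 5 for MES1-GFP, 1 for PFK1-GFP, 8 for PFK2-GFP and 12 for TRP2-GFP. The change in FAS1dMPT-GFP then gave 0, with FAS2 at -5.243, and its totals 108. With mitochondrial features the count was 5 for ARC1-GFP and, against other complexes, 41 for PFK2-GFP and 11 for TRP2-GFP. Without features over non-coding RNA genes it was 2 for MES1-GFP. With the batch as a term it was 1 for PFK1-GFP against other complexes, and TRP2 in SD-trp had -0.03162. Against all YPD totals 335 and 409 genes were called in FAS1dMPT-GFP and FAS1-GFP FAS2dMPT.

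Leaving out 1 library of the strains compared at a time, IP against total counts ran from 1 to 68 for FAS1-GFP, 0 to 409 for FAS2-GFP, 0 to 98 for FAS1dMPT-GFP, 0 to 64 for FAS1-GFP FAS2dMPT, 2 to 31 for GUS1-GFP, 2 to 5 for MES1-GFP, 1 to 4 for ARC1-GFP, 0 to 905 for PFK1-GFP, 10 to 741 for PFK2-GFP and 2 to 11 for TRP2-GFP. FAS1 ran from -0.04404 to 0.2468 in FAS1dMPT-GFP, FAS2 from -2.596 to 1.077 in FAS1-GFP FAS2dMPT and GUS1 from -0.6676 to 0.007155 in GUS1-GFP. Against other complexes counts ran from 1 to 57 for FAS1-GFP, 1 to 4 for FAS2-GFP, 0 to 1 for FAS1dMPT-GFP, 0 to 2 for FAS1-GFP FAS2dMPT, 2 to 4 for GUS1-GFP, 2 to 9 for MES1-GFP, 0 to 177 for PFK1-GFP, 1 to 218 for PFK2-GFP and 1 to 39 for TRP2-GFP. There FAS1 ran from -0.09903 to 0.1919 and FAS2 from -0.02732 to 0.6677 in FAS1dMPT-GFP, FAS1 from -0.02472 to 0.6684 and FAS2 from -2.836 to 0.8375 in FAS1-GFP FAS2dMPT, and GUS1 from -0.1556 to 0.4947 in GUS1-GFP. The change counts ran from 0 to 12 in FAS1dMPT-GFP, with FAS2 from -6.008 to -5.095, and from 1 to 17 in FAS1-GFP FAS2dMPT. Counts for totals ran from 6 to 114 in FAS1dMPT-GFP and from 49 to 145 in FAS1-GFP FAS2dMPT, with FAS1 from -0.295 to 0.3982 in the latter, and TRP2 in SD-trp ran from -0.2195 to 0.1827 without an SD-trp library or the library labelled FAS1-GFP total 2, the 4 omissions made there.

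For NAA10-GFP along NAA15, NAA25-GFP along NAA20, EGD1d11-GFP along EGD1 and EGD1d11 EGD2-GFP along EGD2, onsets were at codons 196, 68, 126 and 95 with a window of 5 codons and 180, 46, 102 and 74 with 30. They were 184, 56, 109 and 87 with a threshold of 1.5 times and 196, 62, 118 and 89 with 3 times. With a baseline of 100 codons NAA25-GFP had 80 and EGD1d11-GFP 115. NAA20-GFP along NAA20, which had no onset, had one at codon 143 with the window of 30 codons. In the mix, leaving out the first and last 15 positions gave 6.122 and 6.835 beyond FAS2.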

Other observations

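Long coding sequences were more frequent in the IP than short ones in each of the 10 replicated strains. The Spearman correlation of coding length with the log2 difference of IP and total was 0.509 to 0.699 over 2296 genes by strain, and 0.736 for the mean of the strains. In the FAS1-GFP FAS2dMPT replicate 2 pair it was -0.43.

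Among features higher in the IP on average were HAC1, the unfolded protein response factor, with a mean log2 difference of 2.37 over 10 strains, LPX1, a peroxisomal lipase, with 2.11, and GCN4, the regulator of amino acid synthesis, with 2.06. These genes were chosen after their values were seen. Summed mitochondrially encoded genes ranged from 239 to 14580 RPM in the totals with values, and log2 ratios of IP over total from -1.83, in the FAS1-GFP FAS2dMPT replicate 2 pair, to 3.71. The labels of that pair may be exchanged, and the lowest ratio of the other pairs was 0.73, in FAS1dMPT-GFP replicate 1.

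For totals in SD-trp against YPD, 0 genes were called by limma, with 337 at an unadjusted p below 0.05 and 43 called with array weights. The count over drawn splits was planned before the result was seen, but with 0 genes called each of the 100 splits of the 20 libraries reaches that number (100 of 100), so it decides nothing about chance. The highest other split called 119 genes and set FAS1-GFP total 2, PFK2-GFP total 2 and TRP3-GFP total 1 apart, which points to a structure of the libraries whose cause was not tested.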
